A study of Mus musculus with 18 samples.

How the data were processed

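Primary mouse astrocyte, microglia and neuron cultures and the small extracellular vesicles (sEVs) they released were profiled by PacBio long-read sequencing of full-length cDNA. There were 6 groups, cells and sEVs of each of the 3 cell types, with 3 libraries in each group and 18 libraries in total. Per the labels' protocols, polyadenylated RNA was converted to cDNA with a single cell/low input kit and reamplified for 10 cycles. Per the labels' protocols, the cell libraries were combined in 1 sequencing pool and the sEV libraries in another, and each pool was run on 2 SMRT cells. Fraction and sequencing pool can therefore not be told apart in any comparison of sEVs with cells.

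The deposited table holds raw read counts per isoform, with a gene symbol, a structural category and subcategory, and an IEJ mark that the sources used here do not explain. Per the submitters' processing notes, reads were mapped to GRCm39 with minimap2. The versions, the isoform caller and the annotation are not given in the sources used here. The table held 114425 isoforms under 17714 gene labels. Of these labels, 1228 were unannotated loci, 661 were read-throughs of neighbouring genes and 2175 were predicted genes or pseudogenes. A RefSeq table of assembly GRCm38.p6 matched 14896 labels by symbol and 25 by synonym only. Its build differs from that of the reads, so no coordinates were used. The smallest value above 0 in the table was 2, so a count of 0 can hide single reads of an isoform.

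Library totals ran from 434298 to 683381 reads and summed to 10234812. Isoforms seen in 1 library only made up 64.5% of all isoforms and 4.93% of the reads. The reads carry no molecular identifiers, so intervals and floors cover counting error only. A count of 0 allows up to 3 reads per library, and folds against a group with 0 reads are given as "at least" that floor.

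Counts were summed over the isoforms of each gene label. Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM normalisation and quasi-likelihood F tests in 1 fit of all 18 libraries with a mean per group. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The filter kept 8184 genes and 9370 isoforms. The common dispersion was 0.310 for genes, a coefficient of variation of 0.556, and 0.681 for isoforms. Levels are given as CPM of TMM-scaled library sizes, as mean ± SD, n = 3, and sums over marker lists as RPM of unscaled library totals. The comparisons were sEVs against their source cells in each cell type, the mean of these over the 3 cell types, the interaction of cell type and fraction, and each cell type against the mean of the other 2 among cells and among sEVs. Isoforms were tested in the same way. Isoform usage was tested with edgeR's diffSpliceDGE and gene-level Simes p-values in 1752 genes with 2 or more tested isoforms. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. The choices of tests, gene lists and naming rule were made before the data were examined.

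Shifts of 28 fixed gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. A list needed 3 tested genes, which 27 lists had, and p-values were adjusted over the 81 pairs of list and cell type. A list's mean shift is the mean log2 difference of its genes minus that of all other tested genes. The marker lists were those of neurons, astrocytes, microglia, the oligodendrocyte lineage, fibroblasts and vessels, blood cells, and ependyma and choroid plexus. Lists on vesicles and RNA were EV biogenesis and surface proteins, RNA sorting proteins, nuclear-retained long non-coding RNAs, spliceosome and nuclear speckle proteins, and signal recognition and ER translocation. Lists on cell state were immediate early genes, heat shock and ER chaperones, disease-associated microglia genes, homeostatic microglia genes, reactive astrocyte genes, interferon response, inflammatory cytokines and chemokines, and cell cycle. The remaining lists were extracellular matrix, actin and tubulin cytoskeleton, synaptic vesicle and postsynaptic genes, cytosolic ribosomal proteins, translation factors, mitochondrially encoded genes, the nuclear-encoded respiratory chain, and histones.

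Genes named for a comparison of sEVs with cells had an adjusted p under 0.05, no overlap between the 3 libraries of each group, and a mean count of 20 or more in the higher group. The 10 largest changes in each direction were taken, or the 10 smallest p-values for the mean contrast and the interaction, and the 5 largest for each cell type against the others. For isoforms and isoform usage the 5 smallest adjusted p-values per cell type were taken. Predicted genes were passed over. A few genes that this rule names are not reported here. Members of the fixed lists were also named as examples of their list.

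Shares of reads per library were compared by exact two-sided permutation tests. The smallest p possible is 0.1 for 3 libraries against 3 and 0.00025 when permuting within the 3 cell types. The file used gives no transcript lengths or exon numbers, so the planned comparison of transcript length was replaced by shares of structural classes of isoforms. Detected genes were counted after each library was thinned at random to 434298 reads.

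The steps were tested on simulated counts with 200 changed genes. For astrocyte sEVs against cells, 4.41% of 2-fold, 36.4% of 4-fold and 69.7% of 16-fold changes were recovered among 7429 tested genes. For microglia these shares were 2.94%, 25.8% and 57.6% of 7560 genes, and for neurons 5.88%, 27.3% and 78.8% of 7456 genes. For the interaction they were 0%, 7.58% and 42.4% of 7156 genes. Changes of 4-fold and less were thus mostly missed in a single cell type in these simulations. The data gave many more calls than 200, and the adjustment of p-values is less strict when more genes change. The shares recovered therefore need not hold for the data. False calls numbered 6 for astrocytes (7.59% of calls), 0 for microglia and 2 for neurons (2.63%).

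The alternatives were DESeq2 1.42.0, library sizes without TMM, no filter on low counts, only the groups compared, the replicate number as a block, leaving out mitochondrially encoded and ribosomal protein genes, thinned libraries, camera with an estimated correlation, fry, gene-level F tests of isoform usage, and leaving out each replicate in turn. Further alternatives were chosen after the data were seen and left out Ftl1 and Gm42047, or 2 libraries in which Gm42047 took many reads. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.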

Results

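Long reads of full-length cDNA were counted per isoform in cells and sEVs of primary mouse astrocyte, microglia and neuron cultures, with n = 3 libraries in each of the 6 groups. The series set out to ask whether sEV mRNA is packaged in a cell type-specific way. The 18 libraries held 434298 to 683381 reads each. After the filter on low counts 8184 genes and 9370 isoforms were tested.

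Each culture carried the transcripts of its cell type. Aqp4, the water channel of astrocyte endfeet, stood at 837 ± 114 CPM in astrocyte cells and at a mean of 7.76 CPM in the other cells. Agt, the angiotensin precursor made by astrocytes, stood at 387 ± 106 against 8.05 CPM, and Gdpd2, a phosphodiesterase of glial cells, at 460 ± 115 against 17.2 CPM. The myelin gene Mbp (2351 ± 1033 against 154 CPM) was also among the 5 largest differences in astrocyte cells. In microglia cells the activation marker Cd69 (21482 ± 2915 CPM), the cytokine genes Il12b (19605 ± 4872 CPM) and Il27 (11607 ± 369 CPM), the chemokine gene Ccl4 (13719 ± 225 CPM) and the macrophage elastase gene Mmp12 (11648 ± 1253 CPM) had 0 reads in the 6 other cell libraries. In neuron cells the synaptotagmin genes Syt4 (1130 ± 908 CPM) and Syt1 (603 ± 60.0 CPM), the vesicle adaptor gene Caly (436 ± 34.0 CPM), the membrane protein gene Tmem130 (387 ± 87.6 CPM) and the AMPA receptor subunit gene Cacng3 (308 ± 95.03 CPM) had 0 reads in the 6 others. These genes had adjusted p-values of 0.000614 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. As Cd69 marks activation, the microglia contrast does not tell cell type apart from activation state.

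Marker lists gave the same picture. Of 19 tested astrocyte markers 18 were higher in astrocyte cells than in the other cells, as were 23 of 23 microglia markers in microglia cells and 22 of 22 neuron markers in neuron cells. Summed astrocyte markers reached 56232 ± 4862 RPM in astrocyte cells and 12379 ± 1064 in neuron cells, where 11 of the 19 markers were higher than in the mean of the other cells. Neuron markers summed to 11685 ± 722 RPM in neuron cells, so the neuron cultures carried both lists at a similar level. In neuron sEVs neuron markers summed to 4755 ± 534 RPM and astrocyte markers to 5721 ± 815. Oligodendrocyte markers summed to 7471 ± 2904 RPM in astrocyte cells and 10 of 12 were higher there. Blood cell markers, with fewer than 3 tested genes, stayed between 0 and 25.3 RPM in every group, and fibroblast and vascular markers between 23.05 and 252.

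By edgeR's test 1298 genes differed between astrocyte cells and the mean of the other cells (881 higher, 417 lower). DESeq2 called 1968 genes (1015 higher, 953 lower), library sizes without TMM gave 1557 higher and 285 lower, and leaving out astrocyte cell replicate 3 left 758. In microglia cells 3472 genes differed (1473 higher, 1999 lower; 1078 and 3346 without TMM) and in neuron cells 2243 (1616 higher, 627 lower; 2217 and 459 without TMM). Without TMM the median log2 difference of all genes was 0.63 in astrocyte, -1.43 in microglia and 0.72 in neuron cells, against 0.24, -0.66 and 0.34 with it.

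**Figure D1:**
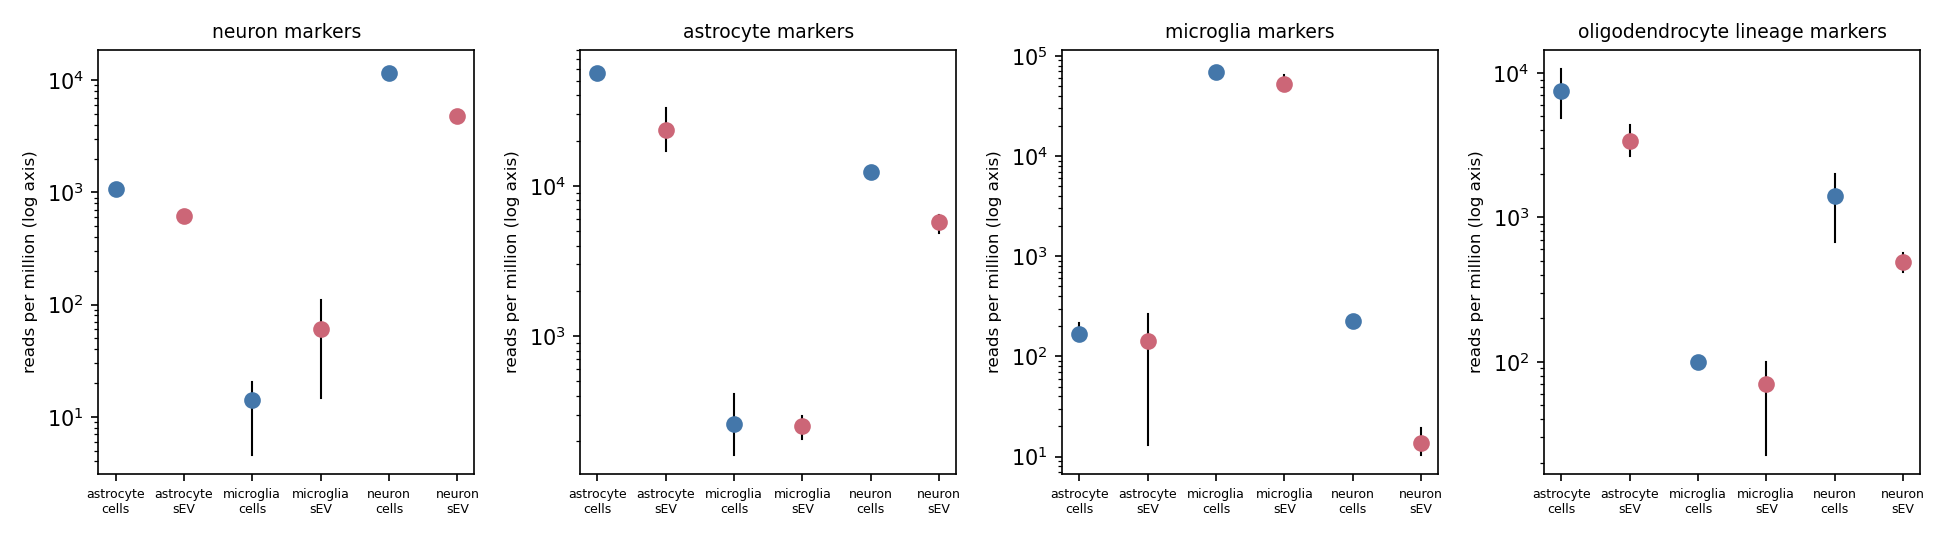
Summed RPM of 4 marker lists in the 6 groups, on a log axis, with dots for the mean of 3 libraries and lines from the lowest to the highest library. Microglia markers sum to 69359 RPM in microglia cells and to 168 and 224 in astrocyte and neuron cells.

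Comparing sEVs with their source cells asks which transcripts are packaged or held back. In astrocytes the largest gains were transcripts with few or 0 reads in the cell libraries. Trak2, an adaptor of mitochondrial transport, stood at 276 ± 71.7 CPM in sEVs with 0 reads in cells, a difference of at least 65.3-fold (adjusted p = 0.00058, edgeR). As the table holds no value of 1, a 0 can hide single reads per isoform, here and in each bound that follows. Wsb2, a ubiquitin ligase adaptor, stood at 1090 ± 381 CPM in sEVs with 6 reads in the 3 cell libraries (adjusted p = 7.34e-05), and Rcc2, a chromosome condensation regulator, rose 181-fold (3212 ± 974 against 17.6 ± 20.5 CPM; adjusted p = 0.000192). The zinc finger gene Sall3 stood at 271 ± 218 CPM in sEVs with 2 reads in the 3 cell libraries (adjusted p = 0.00019). The G protein subunit gene Gna13 had 0 reads in cells and 113 ± 171 CPM in sEVs, mostly from replicate 2, and was still called without that library. Also with 0 reads in cells, the kinase gene Dyrk1a (59.9 ± 59.0 CPM) rose 14.2-fold, Zfp592 (50.4 ± 54.5 CPM) 11.9-fold, the TFIID subunit gene Taf4 9.69-fold, the non-coding AU020206 9.59-fold and the centrosomal Alms1 9.37-fold. The bounds of these 5 genes are likewise "at least" values, and the adjusted p-values of all 6 ran from 0.0023 to 0.0117.

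Among the losses in astrocyte sEVs Dag1, the dystroglycan that anchors endfeet to the basement membrane, stood at 216 ± 32.4 CPM in cells with 0 reads in sEVs, at least 46.3-fold lower (adjusted p = 0.00128, edgeR). Also with 0 sEV reads, the secreted Olfm2 fell at least 37.3-fold (174 ± 100 CPM in cells), the progestin receptor gene Paqr7 at least 32.8-fold, the cholesterol hydroxylase gene Cyp46a1 at least 29.8-fold (139 ± 49.7 CPM) and the GPI transamidase gene Pigt at least 27.3-fold (127 ± 46.3 CPM). The heparan sulphate polymerase gene Ext2 fell at least 24.97-fold, the lysosomal glucosidase gene Gaa at least 23.5-fold (110 ± 49.7 CPM) and Sel1l, of the ER degradation complex, at least 23.1-fold (108 ± 21.3 CPM). The axon guidance gene Sema6d fell at least 35.9-fold (168 ± 25.8 CPM) but was not called by DESeq2. Pbxip1, a PBX-binding protein gene, fell at least 32.0-fold and was lost with DESeq2 and when any of 4 astrocyte libraries was left out.

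In astrocyte sEVs 1660 genes passed (658 higher, 1002 lower) by edgeR's test, and 1595 of them differed over 2-fold. Leaving out astrocyte cell replicate 3 left 1100. The median log2 difference of all genes was 0.

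Cytosolic ribosomal protein transcripts rose in astrocyte sEVs in 50 of 77 tested genes, with 1 lower, or in 58 and 1 adjusted over the list alone. Their mean shift was 1.498 log2 by camera (adjusted p = 1.47e-19; adjusted p = 0.126 with an estimated correlation), and Rplp0, of the ribosomal stalk, rose 5.50-fold (4143 ± 201 against 753 ± 94.0 CPM). Translation factors shifted by 0.49 (11 higher, 1 lower of 55, the same over the list alone; adjusted p = 0.0306 by camera; adjusted p = 0.536 with an estimated correlation), with the elongation factor gene Eef1a1 up 3.88-fold. The nuclear-encoded respiratory chain shifted by 0.48 (7 higher, 5 lower of 76; 6 and 5 over the list alone; adjusted p = 0.0219 by camera; adjusted p = 0.639 with an estimated correlation). Inflammatory cytokines and chemokines shifted by 0.69 (6 higher, 0 lower of 18; 7 over the list alone; adjusted p = 0.04 by camera; adjusted p = 0.497 with an estimated correlation), but at low levels, with the microglial chemokines Ccl3 and Ccl4 at 14.4 ± 12.6 and 14.9 ± 12.96 CPM in sEVs and 0 reads in cells. The respiratory chain, translation factor and cytokine calls were each lost when single astrocyte libraries were left out, and the respiratory chain call also with fry.

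Astrocyte markers themselves were depleted from astrocyte sEVs. Of 19 markers 11 fell and 1 rose, over the list alone as well, with a mean shift of -2.35 (camera adjusted p = 0.000276; adjusted p = 0.136 with an estimated correlation). The gap junction gene Gja1 fell 44.8-fold, the glutamate transporter gene Slc1a3 37.0-fold and the secreted chaperone gene Clu 49.6-fold, whereas the cytosolic lipid carrier gene Fabp7 rose 2.28-fold. Gfap, the cytosolic intermediate filament, was not changed (12437 ± 5049 against 10877 ± 1389 CPM; adjusted p = 0.907, edgeR). Oligodendrocyte markers fell in 7 of 12 genes, 8 over the list alone, with a shift of -2.11 (camera adjusted p = 0.000344; adjusted p = 0.181 with an estimated correlation); the myelin enzyme gene Cnp fell 3.10-fold. Ependymal and choroid markers fell in 3 of 4 genes, 3 over the list alone, with a shift of -2.29 (camera adjusted p = 0.0294; adjusted p = 0.163 with an estimated correlation).

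Further lists were lower in astrocyte sEVs by camera. Heat shock and ER chaperones fell in 10 of 17 genes, also over the list alone, with a shift of -1.76 (camera adjusted p = 3.97e-05; adjusted p = 0.0947 with an estimated correlation), and the ER chaperone genes Hspa5 and Hsp90b1 fell 21.2-fold and 19.9-fold. Signal recognition and ER translocation had 11 lower and 1 higher of 22 genes, 12 and 2 over the list alone, with a shift of -1.44 (camera adjusted p = 0.000344; adjusted p = 0.0947 with an estimated correlation). The glycosyltransferase subunit gene Rpn1 fell 28.4-fold, whereas Srp9, of the cytosolic signal recognition particle, rose 2.73-fold. Extracellular matrix genes had 7 lower and 1 higher of 14, over the list alone as well, with a shift of -2.60 (camera adjusted p = 0.000195; adjusted p = 0.226 with an estimated correlation). The secreted protease inhibitor gene Serpine2 fell 35.6-fold and Sparc, a secreted matrix-binding protein gene, 23.8-fold, and the cytosolic lectin gene Lgals1 rose 5.18-fold. Disease-associated microglia genes had 6 lower and 1 higher of 20 (6 and 2 over the list alone; shift -1.16, camera adjusted p = 0.0299; adjusted p = 0.458 with an estimated correlation), and this call was lost without astrocyte sEV replicate 1. Reactive astrocyte genes had 4 lower and 1 higher of 12, over the list alone as well (shift -1.57, camera adjusted p = 0.018; adjusted p = 0.163 with an estimated correlation), the MHC class I gene H2-D1 falling 18.4-fold.

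Mitochondrially encoded transcripts fell in 7 of 11 genes, 7 over the list alone, with a shift of -3.47 (camera adjusted p = 0.0048; adjusted p = 0.259 with an estimated correlation), and mt-Co1, of complex IV, fell 22.4-fold. Spliceosome and nuclear speckle genes had 8 lower and 1 higher of 24, 9 and 2 over the list alone, with a shift of -0.57 (camera adjusted p = 0.0489; adjusted p = 0.497 with an estimated correlation). That call was lost without TMM (adjusted p = 0.0577 by camera), with the replicate block and in 11 of 18 fits leaving out 1 library. The splicing factor gene Srsf5 fell 4.03-fold and the speckle scaffold gene Son rose 14.4-fold.

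The other lists were not shifted in astrocyte sEVs by camera, with adjusted p-values from 0.121 to 0.95. Of 23 EV biogenesis and surface genes 4 fell, over the list alone as well, among them the tetraspanin genes Cd9 (20.5-fold), Cd63 (13.8-fold) and Cd81 (12.3-fold). RNA sorting proteins had 2 higher and 3 lower of 16, with the cold shock protein gene Ybx1 up 11.2-fold and the ribonucleoprotein gene Hnrnpa2b1 down 3.13-fold. Nuclear-retained RNAs had 1 higher and 2 lower of 9, with Malat1 of nuclear speckles down 7.04-fold and the cytoplasmic Norad up 5.66-fold. Immediate early genes had 5 lower of 11, interferon response genes 4 higher and 1 lower of 19, cell cycle genes 2 higher of 19, and actin and tubulin genes 7 higher and 3 lower of 25. Microglia markers had 3 higher and 1 lower of 23, homeostatic microglia genes 1 higher and 2 lower of 8, neuron markers 2 lower of 22, synaptic genes 1 higher and 2 lower of 18, histones 1 lower of 11, and fibroblast and vascular markers 0 of 3. Microglia markers were called without the 2 libraries rich in Gm42047, a setting chosen after the data were seen (shift 0.75, adjusted p = 0.0244 by camera).

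Among the gains in microglia sEVs Mbd2, a methyl-CpG binding protein gene, stood at 77.4 ± 5.03 CPM in sEVs with 0 reads in cells, at least 9.31-fold higher (adjusted p = 0.00773, edgeR). Also with 0 reads in cells, the ubiquitin ligase gene Fbxo11 rose at least 5.62-fold, the Golgi protein gene Acbd3 at least 5.24-fold and the chromatin remodeller gene Phf10 at least 4.96-fold. The motor protein gene Myo5a (86.4 ± 49.8 CPM in sEVs), the actin regulator gene Daam1 (70.5 ± 42.0 CPM) and the RNA methylation reader gene Ythdc1 (75.1 ± 53.0 CPM) rose from 8, 4 and 7 reads in the 3 cell libraries, too few for a fold. The lipid carrier gene Pitpna rose 8.96-fold (80.7 ± 24.4 against 8.53 ± 8.06 CPM, from 10 reads in cells). The lysosomal fusion gene Ccz1 (48.1 ± 29.7 CPM) and the phosphatase gene Ppp2cb (40.2 ± 37.4 CPM) had 2 reads each in cells. Calls for Acbd3, Ythdc1, Ccz1, Daam1, Myo5a and Ppp2cb were lost when single libraries were left out, and those of Acbd3 and Ythdc1 also with a replicate block.

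Among the losses in microglia sEVs Mgat1, the Golgi enzyme that starts complex N-glycans, stood at 486 ± 41.3 CPM in cells with 0 reads in sEVs, at least 90.1-fold lower (adjusted p = 0.00208, edgeR). Also with 0 sEV reads, the fibronectin receptor gene Itga5 fell at least 51.8-fold (280 ± 90.7 CPM in cells), the collagen chaperone gene Serpinh1 at least 41.4-fold (224 ± 171 CPM), the lysosomal phospholipase gene Plbd2 at least 37.0-fold (200 ± 18.6 CPM) and the translocon gene Sec61a1 at least 29.9-fold (161 ± 19.9 CPM). The sterol demethylase gene Cyp51 fell at least 21.6-fold (116 ± 24.1 CPM) and the microglial growth factor gene Csf1 at least 20.6-fold (111 ± 50.4 CPM). The cytokine signalling inhibitor gene Socs3 (at least 40.0-fold), the helicase gene Znfx1 (at least 38.8-fold) and Itgam, which encodes CD11b (at least 30.0-fold), were not called by DESeq2.

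In microglia sEVs 972 genes passed (221 higher, 751 lower) by edgeR's test, and 938 differed over 2-fold. Without TMM the split was 666 higher and 519 lower, with a median log2 difference of all genes of 0.14 in place of 0. With only the 2 groups in the fit, which changes the filter, dispersion and scaling at once, it was 415 and 606. Leaving out microglia cell replicate 2 left 583 genes.

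Ribosomal protein transcripts rose in microglia sEVs in 22 of 77 genes and fell in 0, with 33 higher over the list alone and a mean shift of 1.09 (camera adjusted p = 4.45e-16; adjusted p = 0.137 with an estimated correlation). The respiratory chain had 20 higher and 1 lower of 76, 27 and 4 over the list alone, with a shift of 0.89 (camera adjusted p = 2.03e-08; adjusted p = 0.276 with an estimated correlation), the cytochrome oxidase gene Cox6c rising by 2.40 log2. Histones had 4 higher and 1 lower of 11, 5 and 1 over the list alone, with a shift of 0.84 (camera adjusted p = 0.0179; adjusted p = 0.164 with an estimated correlation). The linker histone gene H1f0 rose 3.88-fold and H3f3b, a replacement histone gene, 1.96-fold, and the list's call was lost without microglia sEV replicate 1.

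Microglia markers fell in their own sEVs, with 11 lower and 1 higher of 23, 13 and 1 over the list alone, and a shift of -1.45 (camera adjusted p = 2.81e-06; adjusted p = 0.126 with an estimated correlation). The CSF1 receptor gene Csf1r fell 32.3-fold, the cathepsin gene Ctss 6.88-fold and the endotoxin co-receptor gene Cd14 4.61-fold, whereas Aif1, a cytosolic calcium-binding protein gene, rose 3.49-fold. Disease-associated microglia genes fell in 10 of 20 (13 lower and 1 higher over the list alone; shift -1.86, camera adjusted p = 1.68e-06; adjusted p = 0.116 with an estimated correlation), with secreted Apoe down 5.96-fold and Spp1 7.48-fold. Homeostatic microglia genes fell in 4 of 8, 5 over the list alone (shift -1.9995, camera adjusted p = 0.0048; adjusted p = 0.101 with an estimated correlation). Reactive astrocyte genes fell in 4 of 12, 6 over the list alone (shift -1.41, camera adjusted p = 0.00134; adjusted p = 0.101 with an estimated correlation), with H2-D1 down 12.997-fold and the hyaluronan receptor gene Cd44 13.9-fold. Immediate early genes fell in 5 of 11, also over the list alone (shift -1.68, camera adjusted p = 0.00157; adjusted p = 0.0947 with an estimated correlation), with the transcription factor gene Junb down 24.2-fold.

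Heat shock and ER chaperones fell in 9 of 17 microglia genes (9 lower and 2 higher over the list alone; shift -1.24, camera adjusted p = 0.000732; adjusted p = 0.126 with an estimated correlation), with Hspa5 down 13.7-fold. Signal recognition and ER translocation had 10 lower and 1 higher of 22 (11 and 1 over the list alone; shift -0.84, camera adjusted p = 0.0295; adjusted p = 0.126 with an estimated correlation), and the call was lost without TMM (adjusted p = 0.122 by camera) and without microglia sEV replicate 2 or 3. Matrix genes fell in 8 of 14, 9 over the list alone (shift -2.13, camera adjusted p = 9.96e-05; adjusted p = 0.213 with an estimated correlation). Fibroblast and vascular markers fell in 3 of 3, over the list alone as well (shift -3.09, camera adjusted p = 0.0151; adjusted p = 0.164 with an estimated correlation), among them the matrix proteoglycan gene Dcn. Mitochondrially encoded genes fell in 5 of 11 (7 lower and 1 higher over the list alone; shift -2.21, camera adjusted p = 0.0185; adjusted p = 0.372 with an estimated correlation), mt-Co1 by 13.5-fold.

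Lists with no shift in microglia sEVs by camera had adjusted p-values from 0.0678 to 0.95. Cytokines and chemokines had 4 lower of 18, with Tnf down 3.87-fold, and interferon response genes 1 lower of 19, the antiviral gene Rsad2, down 85.6-fold. EV biogenesis genes had 5 lower of 23, with Cd9 down 8.15-fold, RNA sorting proteins 2 higher of 16, with Ybx1 up 6.16-fold, and nuclear-retained RNAs 1 lower of 9, Malat1, down 111-fold. Actin and tubulin genes had 4 higher and 2 lower of 25, the actin gene Actb falling 191-fold and the monomer-binding thymosin gene Tmsb4x rising 2.71-fold. Translation factors had 2 lower of 55, spliceosome genes 1 lower of 24, cell cycle genes 1 lower of 19, ependymal markers 2 lower of 4, astrocyte markers 4 lower of 19, neuron markers 2 higher of 22, and oligodendrocyte markers and synaptic genes 0 of 12 and 0 of 18. Without TMM the shifts of translation factors (adjusted p = 0.000973), RNA sorting proteins (adjusted p = 0.0321) and ependymal and choroid markers (-1.90, adjusted p = 0.0321) were called by camera.

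In neurons Rcc2 stood at 5598 ± 4419 CPM in sEVs with 0 reads in cells, at least 1179-fold higher (adjusted p = 1.33e-05, edgeR), and Sall3 at 143 ± 40.5 CPM, at least 30.1-fold higher. The membrane skeleton gene Epb41 rose at least 29.1-fold (138 ± 11.1 CPM). Among further genes with 0 reads in cells Zfp704 rose at least 21.7-fold (103 ± 62.8 CPM), Zfp219 at least 20.9-fold (99.3 ± 28.6 CPM), the chromatin gene Gatad1 at least 20.4-fold, the histone methyltransferase gene Kmt5a at least 19.6-fold and Thap12 at least 18.7-fold. The neural crest regulator gene Kctd15 rose at least 31.2-fold (148 ± 23.6 CPM) but was not called by DESeq2. The forkhead gene Foxj3 rose at least 18.5-fold and was lost without neuron cell replicate 2.

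Among the losses in neuron sEVs, with 0 sEV reads, Tmem130 fell at least 69.7-fold (387 ± 87.6 CPM in cells; adjusted p = 0.000104, edgeR), the vesicle protein gene Synpr at least 61.8-fold (343 ± 152 CPM), the secretory carrier gene Scamp5 at least 59.4-fold (329 ± 28.2 CPM) and the membrane-bound chemokine gene Cx3cl1 at least 59.4-fold (329 ± 47.5 CPM). The secreted plasminogen activator gene Plat fell at least 38.2-fold (212 ± 18.999 CPM). Syt4 (at least 204-fold), the secretogranin gene Scg2 (at least 56.0-fold) and the synaptophysin gene Syp (at least 43.4-fold) were not called by DESeq2.

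In neuron sEVs 2570 genes passed (1117 higher, 1453 lower) by edgeR's test and 2502 differed over 2-fold. Without TMM the split was 866 higher and 1906 lower, with a median log2 difference of all genes of -0.47 in place of -0.10.

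Ribosomal protein transcripts rose in neuron sEVs in 66 of 77 genes and fell in 0, or 69 and 1 over the list alone, with a mean shift of 2.75 (camera adjusted p = 2.48e-31; adjusted p = 0.0947 with an estimated correlation). Rps2, of the small subunit, rose 18.1-fold (13323 ± 1515 against 736 ± 216 CPM). The respiratory chain had 46 higher and 4 lower of 76, 52 and 4 over the list alone, with a shift of 1.41 (camera adjusted p = 1.66e-10; adjusted p = 0.217 with an estimated correlation), Ndufa4 rising 2.21-fold. Translation factors had 20 higher and 4 lower of 55, over the list alone as well, with a shift of 0.77 (camera adjusted p = 0.00693; adjusted p = 0.458 with an estimated correlation), Eef1a1 rising 6.81-fold.

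Neuron markers had 11 lower and 1 higher of 22, over the list alone as well, with a shift of -1.83 (camera adjusted p = 0.000506; adjusted p = 0.137 with an estimated correlation). The AMPA receptor gene Gria2 fell 29.0-fold, the surface glycoprotein gene Thy1 21.4-fold and the SNARE gene Snap25 7.88-fold, whereas the microtubule-binding tau gene Mapt rose 2.19-fold. Synaptic vesicle and postsynaptic genes had 11 lower and 1 higher of 18, over the list alone as well, with a shift of -2.63 (camera adjusted p = 5.3e-05; adjusted p = 0.0947 with an estimated correlation), and the cytosolic complexin gene Cplx1 was the 1 that rose (146 ± 42.1 against 2.07 ± 1.80 CPM). Heat shock and ER chaperones had 12 lower and 1 higher of 17, 13 and 1 over the list alone, with a shift of -2.27 (camera adjusted p = 3.31e-05; adjusted p = 0.0947 with an estimated correlation), Hspa5 falling 43.8-fold. Matrix genes had 9 lower and 1 higher of 14, 10 and 1 over the list alone (shift -2.36, camera adjusted p = 0.0048; adjusted p = 0.394 with an estimated correlation), Serpine2 falling 23.3-fold.

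Signal recognition and ER translocation had 9 lower and 2 higher of 22 in neuron sEVs, 10 and 2 over the list alone (shift -1.16, camera adjusted p = 0.0371; adjusted p = 0.136 with an estimated correlation), Rpn1 falling 24.0-fold, and the call was lost without neuron sEV replicate 2. Spliceosome genes had 12 lower and 3 higher of 24, over the list alone as well (shift -0.94, camera adjusted p = 0.0313; adjusted p = 0.466 with an estimated correlation), Srsf5 falling 16.5-fold and Son rising 15.7-fold, and the call was lost in 7 of 18 fits leaving out 1 library. Mitochondrially encoded genes fell in 7 of 11, also over the list alone (shift -3.08, camera adjusted p = 0.0445; adjusted p = 0.465 with an estimated correlation), mt-Co1 by 16.2-fold. That call was lost without TMM (adjusted p = 0.0615 by camera), with the replicate block and in 4 of 18 fits leaving out 1 library.

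Lists with no shift in neuron sEVs by camera had adjusted p-values from 0.079 to 0.993. EV biogenesis genes had 3 higher and 7 lower of 23, with Cd9 down 22.8-fold, and were called without TMM (adjusted p = 0.0444 by camera). RNA sorting proteins had 2 higher and 3 lower of 16, with Ybx1 up 42.2-fold (7635 ± 2378 against 181 ± 37.3 CPM). Nuclear-retained RNAs had 1 higher and 3 lower of 9, with Malat1 down 27.6-fold and the imprinted Meg3 629-fold. Astrocyte markers had 4 higher and 10 lower of 19, oligodendrocyte markers 4 lower of 12, ependymal markers 2 lower of 4, disease-associated microglia genes 1 higher and 7 lower of 20, and reactive astrocyte genes 5 lower of 12. Immediate early genes had 1 higher and 4 lower of 11, actin and tubulin genes 7 higher and 3 lower of 25, cell cycle genes 2 higher and 1 lower of 19, histones 2 and 2 of 11, homeostatic microglia genes 1 and 2 of 8, and microglia markers 2 lower of 23. Interferon response, cytokine, and fibroblast and vascular genes had 0 calls.

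**Figure D2:**
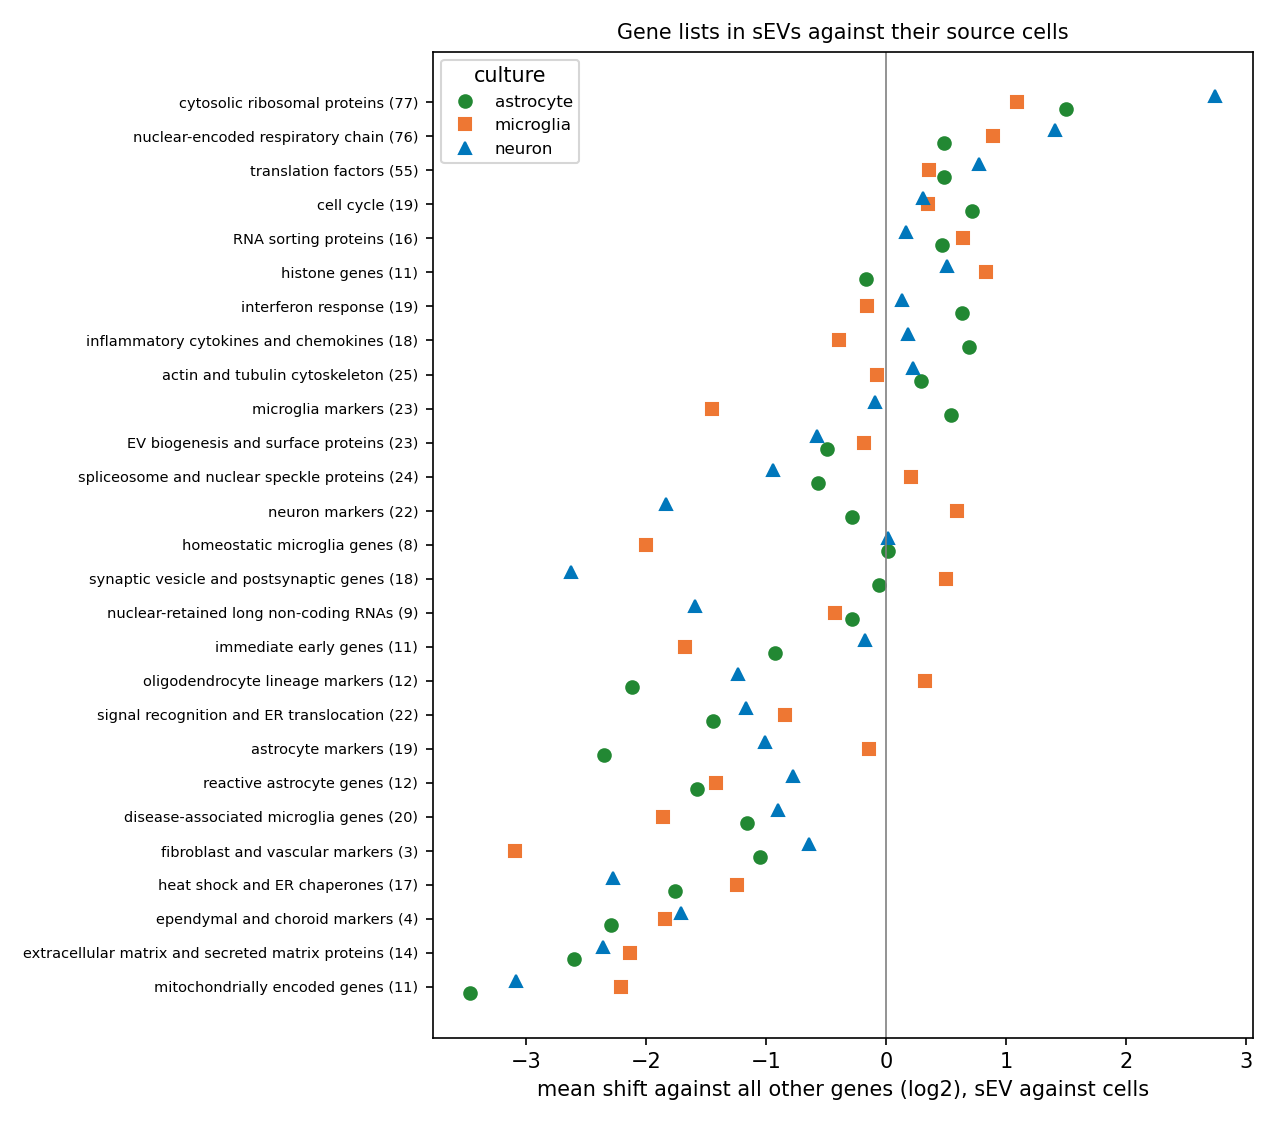
Mean shift of 27 gene lists in sEVs against their source cells (log2, relative to all other tested genes), 1 point per culture, with the number of tested genes in brackets. Ribosomal protein genes lie at 1.498, 1.09 and 2.75 in astrocytes, microglia and neurons, and heat shock and ER chaperones at -1.76, -1.24 and -2.27.

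The mean of the 3 differences asks what is common to the cultures. The 10 genes with the smallest p-values all fell in sEVs. Pdia6, a disulphide isomerase of the ER, fell 16.3-fold (log2 difference -4.02 ± 0.15 SE; adjusted p = 1.04e-11, edgeR), the ER chaperone gene Hspa5 23.4-fold and the isomerase gene Pdia3 21.2-fold. The membrane glycoprotein gene Bsg fell 11.6-fold, the thioredoxin gene Tmx1 12.01-fold, the cargo receptor gene Tmed9 10.9-fold, the lysosomal protease gene Ctsd 14.4-fold, the membrane protein gene Itm2b 14.96-fold and the gamma-secretase gene Ncstn 22.2-fold. Rsrp1, a nuclear serine-rich protein gene, fell 32.3-fold. In all, 2778 genes passed (1183 higher, 1595 lower).

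The same genes recurred between cultures. Of the genes called higher, astrocytes and neurons shared 509 (89.8 expected if independent), astrocytes and microglia 111 (17.8), microglia and neurons 145 (30.2), and all 3 shared 98 (2.43). Of those called lower, astrocytes and neurons shared 736 (178), astrocytes and microglia 421 (91.9), microglia and neurons 437 (133.3), and all 3 shared 368 (16.3). The log2 differences of 8184 genes correlated with Pearson's r = 0.65 between astrocytes and neurons, 0.37 between astrocytes and microglia and 0.33 between microglia and neurons; genes are not independent replicates, so no p is given. Among genes with a mean count of 20 or more these were 0.74, 0.44 and 0.42. Expression in astrocyte sEVs correlated more with neuron sEVs (r = 0.774) than with astrocyte cells (r = 0.674). Astrocyte and neuron cells correlated with each other almost as much (r = 0.764), and the neuron cultures carried astrocyte markers. Neuron sEVs correlated with neuron cells at r = 0.559, whereas microglia sEVs stayed close to microglia cells (r = 0.858).

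The interaction asks which transcripts are packaged differently by cell type. Cell type here includes the state of each culture, such as any activation of the microglia. Stradb, a pseudokinase gene of the LKB1 complex, rose in sEVs of astrocytes (1084 ± 331 against 26.3 ± 5.35 CPM) and neurons (2154 ± 821 against 57.0 ± 18.7 CPM) and had 0 reads in microglia sEVs against 14.04 ± 4.26 CPM in their cells (adjusted p = 0.000106, edgeR). The non-coding AI506816 (58.2 ± 9.51 CPM in cells; adjusted p = 0.000108) and Cdip1, a p53 target gene (18.3 ± 4.09 CPM; adjusted p = 0.000112), were also without reads in microglia sEVs, whereas in neuron sEVs they rose by 2.08 and 1.41 log2. In the 3 microglia cell libraries Stradb, AI506816 and Cdip1 had only 15, 64 and 20 reads. A count of 0 allows up to 3 reads per library, so the microglia values of Stradb and Cdip1 lie near the floor. Ftl1, the ferritin light chain, rose by 5.60 log2 in astrocytes and 5.18 in neurons but was not called in microglia (0.93 log2; adjusted p = 0.0938). The ribosomal protein genes Rpl9 (2.74, 0.77 and 3.97 log2 in astrocytes, microglia and neurons), Rplp0 (2.46, 0.61 and 3.68), Rps2 (2.94, 0.34 and 4.18) and Rpl8 (2.66, 0.54 and 3.87) differed in the same order, as did the kinase gene Csnk1d (1.97, -0.47 and 3.24) and the kinase-anchoring gene Gskip (3.63, 0.79 and 4.38). The size of these differences depends on scaling. TMM factors were 0.639 to 0.721 in microglia cells and 0.933 to 1.15 in microglia sEVs, which lowers the microglia differences. In neurons they were 1.17 in cells and 0.903 to 0.908 in sEVs, which raises the neuron differences. In unscaled shares of reads Ftl1 was at least 4.47% in microglia sEV libraries and at most 2.16% in microglia cell libraries.

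By edgeR's F test 324 genes had a sEV-cell difference that depended on the cell type. The number moved between settings, with 1001 genes by DESeq2, 714 without the filter on low counts, 664 without TMM and 149 without neuron cell replicate 3. All 10 named genes were called in every setting that kept the gene (75 of 75, and 180 of 180 leaving out 1 library). Of the lists, the synaptic genes differed between cultures also with an estimated correlation, by 2.57 log2 between astrocytes and neurons (adjusted p = 0.027 by camera) and by 3.13 between microglia and neurons (adjusted p = 0.0461). Of these 18 genes 15 had 0 reads in microglia cells and 7 in astrocyte cells, where no fall can be seen, so the difference need not be one of packaging.

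Whether sEVs tell their source apart was asked by comparing each sEV group with the other 2. In astrocyte sEVs Mbp stood at 1430 ± 401 CPM against a mean of 4.98 CPM in the others. The transcriptional repressor gene Zbtb5 (182 ± 78.0 CPM), the glial growth factor gene Cntf (48.6 ± 32.5 CPM) and the membrane protein gene Tmem88b (36.5 ± 43.2 CPM) had 0 reads there. Mbp belongs to the oligodendrocyte markers, which summed to 3383 ± 869 RPM in astrocyte sEVs, so its source need not be astrocytes. Zbtb5 had 21 reads in astrocyte cells and 37 in all cell libraries, so it was not confined to astrocyte cells. In microglia sEVs the interferon-inducible Ifi211 (4608 ± 690 CPM) and Tgtp2 (3350 ± 972 CPM), the inhibitory receptor gene Lilrb4a (3146 ± 600 CPM) and the growth regulator gene Slfn2 (2690 ± 437 CPM) had 0 reads in the 6 others, and Il1a (10020 ± 1385 CPM) had 3. In neuron sEVs the kinesin gene Kif5a (995 ± 301 CPM), the membrane-shaping Palm (305 ± 77.8 CPM), the neuropeptide gene Cck (225 ± 67.7 CPM), the non-coding Rian (183 ± 58.0 CPM) and the calcium sensor gene Caln1 (161 ± 53.8 CPM) had 0 reads in the others. The adjusted p-values of these genes were 0.00782 or less by edgeR's test. Of their own markers, 17 of 19 were higher in astrocyte, 22 of 23 in microglia and 18 of 22 in neuron sEVs than in the mean of the others.

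In astrocyte sEVs 1636 genes differed from the other sEVs (1166 higher, 470 lower), in microglia sEVs 4089 (1660 and 2429) and in neuron sEVs 3176 (2191 and 985). For astrocyte sEVs DESeq2 gave 1285 higher and 1079 lower, and library sizes without TMM 1698 and 338 with a median log2 difference of 0.59 in place of 0.31. For neuron sEVs that median was 0.09 without TMM and 0.35 with it.

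A few genes took much of the sEV reads. Ftl1 held 23.2 ± 7.19% of reads in astrocyte sEVs against 0.491 ± 0.0611% in cells, 19.2 ± 4.12% against 0.686 ± 0.00586% in neurons and 5.30 ± 1.42% against 1.84 ± 0.281% in microglia. Cytosolic ribosomal protein genes held 3.57 ± 0.609% against 1.12 ± 0.231% in astrocytes, 1.89 ± 0.424% against 0.757 ± 0.0823% in microglia and 8.70 ± 0.715% against 1.30 ± 0.0400% in neurons. Mitochondrially encoded genes fell from 6.08 ± 1.44% of reads in astrocyte cells to 0.333 ± 0.278% in sEVs, from 0.997 ± 0.155% to 0.116 ± 0.0660% in microglia and from 6.15 ± 1.39% to 0.335 ± 0.207% in neurons. In each of these 9 comparisons the 3 sEV libraries lay apart from the 3 cell libraries (exact two-sided permutation p = 0.1, the smallest possible). Over the 3 cell types the mean differences were 14.9 points for Ftl1, 3.66 for ribosomal protein and -4.15 for mitochondrially encoded genes (exact two-sided permutation p = 0.00025 each, the smallest possible).

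**Figure D3:**
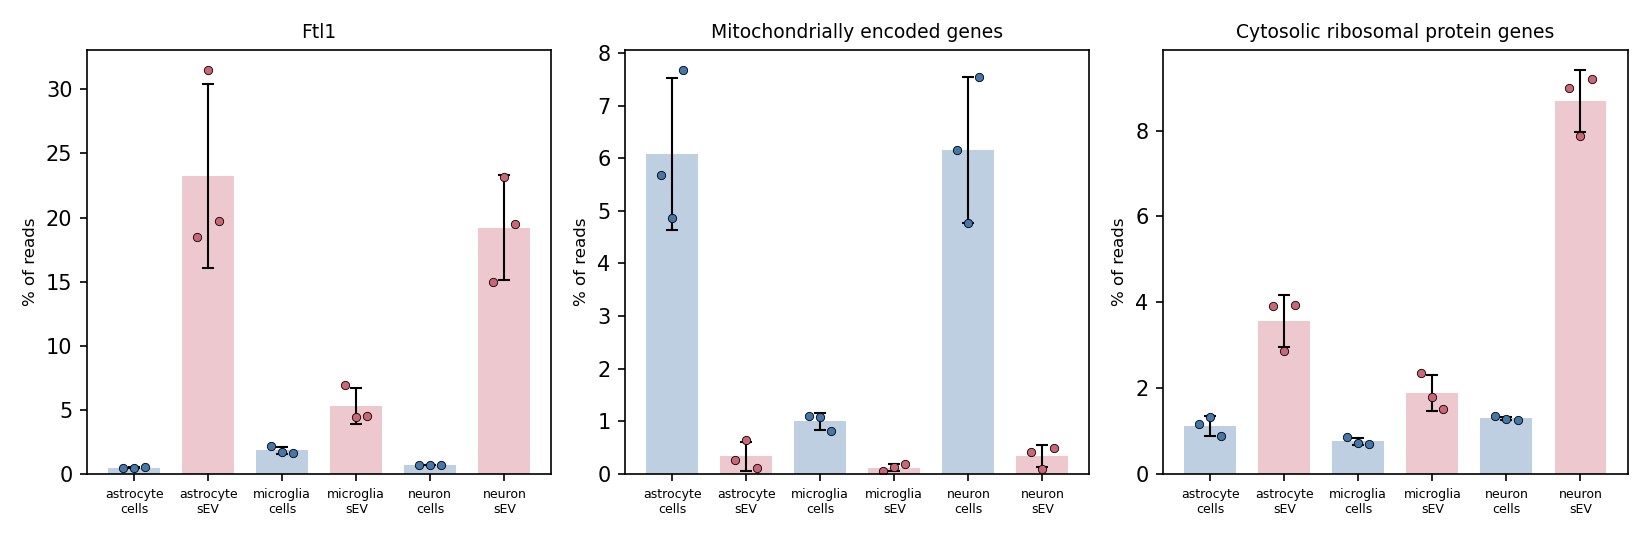
Percent of reads on Ftl1, mitochondrially encoded and cytosolic ribosomal protein genes in the 6 groups, with bars for the mean, error bars for the SD and points for the 3 libraries. Ftl1 holds 23.2% and 19.2% of reads in astrocyte and neuron sEVs and under 2% in each group of cells.

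Full-length reads also show which isoforms reach sEVs. The main Ftl1 isoform rose from 4359 to 194923 CPM in astrocyte sEVs (adjusted p = 1.57e-06, edgeR), and the Rplp0 isoform from 1101 to 11341 CPM in neuron sEVs. Full-splice-match isoforms of Hspa5 and Pdia6 fell in all 3 cultures, that of Hspa5 from 1765 to 76.0 CPM in astrocytes, 6780 to 448 in microglia and 1685 to 32.9 in neurons. That of Pdia6 fell from 895 to 41.0 CPM, 943 to 87.0 and 1227 to 49.9. Isoforms of the signal peptidase gene Spcs2 fell in astrocytes (1336 to 133 CPM) and neurons (989 to 90.3 CPM), and one of the membrane protein gene Grina had 382 CPM in astrocyte cells and 0 reads in sEVs. In microglia isoforms of Ctsd (16544 to 849 CPM) and the ER chaperone gene Calr (917 to 123.2 CPM) and the mono-exonic Malat1 (4432 to 38.3 CPM) fell. In neurons an isoform of D8Ertd738e had 0 reads in cells and 397 CPM in sEVs.

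By edgeR's test 1456 of 9370 isoforms passed in astrocytes (302 higher, 1154 lower), 877 in microglia (127 and 750) and 2544 in neurons (587 and 1957). Leaving out astrocyte cell replicate 3 left 715, microglia cell replicate 2 left 318 and neuron cell replicate 1 left 1284, and the replicate block left 499 in microglia. For neurons DESeq2 gave 986 higher and 1813 lower, and no filter on low counts gave 1617 isoforms (545 and 1072). Of 496 tested 3′ fragments of known transcripts, 47 were higher and 18 lower in neuron sEVs and 23 and 4 in astrocyte sEVs, but 3 and 8 in microglia sEVs. Of 7256 full-splice matches 217 were higher and 982 lower in astrocytes, 116 and 622 in microglia, and 436 and 1687 in neurons.

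Isoform shares within genes were compared next. In astrocytes the mono-exonic isoform of the metallothionein gene Mt1 made up 58.3 ± 3.66% of its reads in cells and 0% in sEVs (adjusted p = 0.000181 by edgeR's diffSpliceDGE). The mono-exonic isoform of Trim35, a ubiquitin ligase gene, went from 18.9 ± 7.68% to 0% in astrocytes and from 28.2 ± 5.82% to 0% in neurons. An intron-retaining Srsf5 isoform went from 46.1 ± 0.483% in astrocyte cells to 0% (adjusted p = 0.00126, diffSpliceDGE of edgeR). A minor Ftl1 isoform went from 0.453 ± 0.384% to 0.00472 ± 0.00361%, and the non-coding Meg3 was also called. Without the filter on low counts the astrocyte calls of Ftl1, Trim35 and Meg3 were lost.

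In microglia an intron-retaining isoform of Ccl4 made up 5.69 ± 0.361% of its reads in cells and 0% in sEVs (adjusted p = 7.55e-06, edgeR's diffSpliceDGE), and one of Il27 2.70 ± 0.279% and 0%. The leading Rsrp1 isoform went from 70.1 ± 5.16% to 0.517 ± 0.895%, while its reference match went from 9.73 ± 6.36% to 81.5 ± 1.33%. An isoform of the interferon-induced GTPase gene Gbp9 went from 31.6 ± 4.29% to 0%. A minor isoform of the antiviral gene Ifit3 went from 1.71 ± 0.455% to 0%, a call lost in 16 of 18 fits leaving out 1 library. In neurons an isoform of the transcription regulator gene Tsc22d1 went from 1.92 ± 0.893% to 36.5 ± 5.20% (adjusted p = 0.00367), one of the adhesion gene Ntm from 27.2 ± 2.84% to 0%, and 3′ fragments of Wdr6 and of the phosphatase gene Minpp1 from 0% to 97.9 ± 3.55% and 53.3 ± 50.3%. These 4 neuron calls were lost when any 1 neuron cell library was left out.

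Isoform usage passed in 35 genes in astrocytes, 42 in microglia and 35 in neurons of 1752. The numbers moved widely, with 142, 91 and 201 by gene-level F tests, 9 and 16 in astrocytes and microglia without the filter on low counts, and 18 and 14 in microglia and neurons with the replicate block. Leaving out astrocyte cell replicate 3, microglia sEV replicate 1 and neuron cell replicate 1 left 6, 8 and 2 genes in these comparisons.

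Isoform structure shifted in the reads as a whole. Full-splice matches made up 81.7 ± 3.29% of reads in astrocyte sEVs against 89.2 ± 0.595% in cells, 86.3 ± 2.80% against 91.5 ± 0.391% in microglia and 77.5 ± 3.27% against 85.9 ± 1.42% in neurons. Their mean difference was -7.02 points (exact two-sided permutation p = 0.00025, the smallest possible). With Ftl1 left out, a setting chosen after the data were seen, it was -13.05 points in astrocytes and -13.6 in neurons, and with each isoform counted once -1.84 points in astrocytes. Fragments of the 3′ end made up 7.14 ± 1.04% against 2.69 ± 0.0772% in astrocytes, 4.67 ± 1.21% against 1.60 ± 0.0293% in microglia and 9.94 ± 0.387% against 3.83 ± 1.38% in neurons, a mean difference of 4.55 points (exact two-sided permutation p = 0.00025). With each isoform counted once the 3 differences were 7.80, 7.13 and 12.3 points, and without Ftl1 6.71 points in astrocytes. Mono-exonic full-splice matches fell by 4.50 points in the mean (exact two-sided permutation p = 0.00025). Reads retaining introns fell by 0.408 points in the mean (exact two-sided permutation p = 0.00575, with 0.00025 the smallest possible). Their difference was -0.691 points in microglia, -0.424 in astrocytes and only -0.110 in neurons (exact two-sided permutation p = 0.1, 0.2 and 0.7). The share of mitochondrially encoded genes moved by -4.15 points over the same libraries, and of 272 tested mono-exonic full-splice matches 34 were higher and 29 lower in astrocyte sEVs, 4 and 24 in microglia and 51 and 37 in neurons.

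At an equal depth of 434298 reads fewer genes were detected in sEVs, 8119 ± 877 against 9273 ± 70.7 in astrocytes and 8469 ± 416 against 9938 ± 192 in neurons (exact two-sided permutation p = 0.1 each, the smallest possible). Only total reads were made equal. Ftl1 held 23.2% and 19.2% of reads in astrocyte and neuron sEVs, which left fewer reads for other genes there than in cells. In microglia the libraries of sEVs and cells overlapped, with 6239 ± 812 against 6818 ± 419 genes (exact two-sided permutation p = 0.4), and with 3 libraries a side no culture alone can pass 0.05. The mean difference was -1067 genes (exact two-sided permutation p = 0.00175, with 0.00025 the smallest possible). In microglia it lay between -946 and -143 genes as single libraries were left out, and in astrocytes between -1559 and -688.

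**Figure D4:**
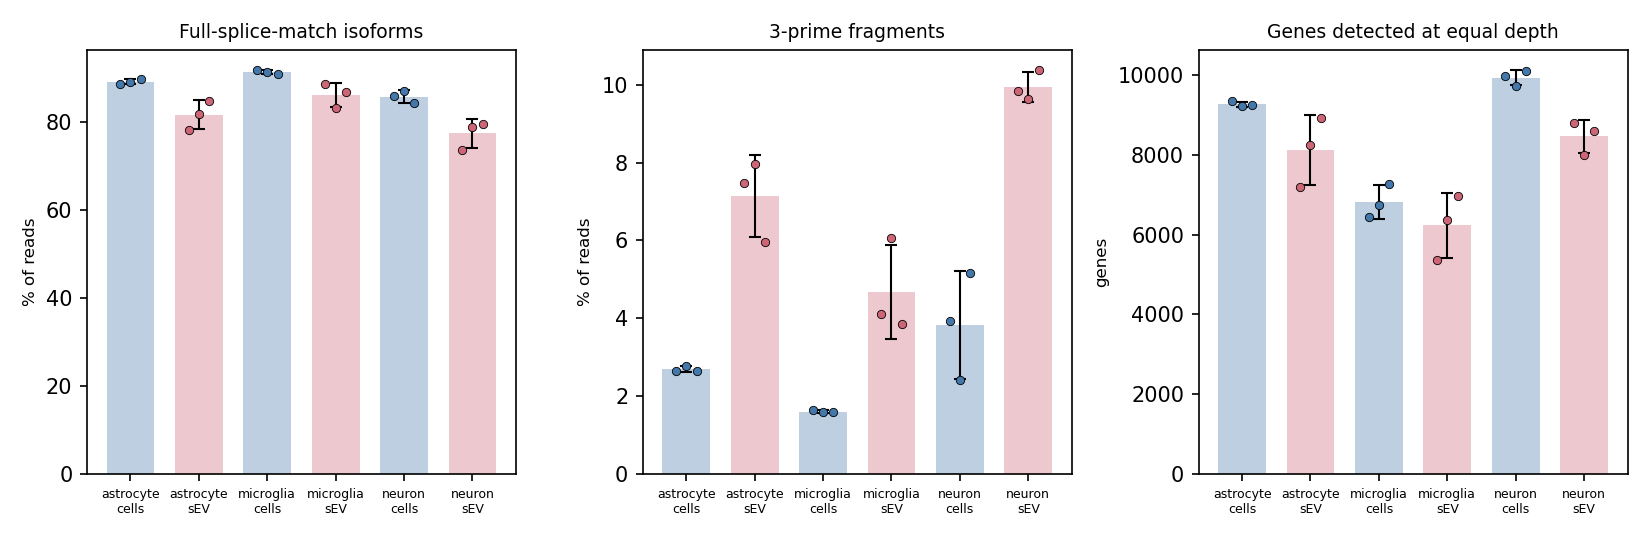
Percent of reads on full-splice-match isoforms and on 3′ fragments, and number of genes detected at equal depth, in the 6 groups, with bars for the mean, error bars for the SD and points for the 3 libraries. Full-splice matches are lower and 3′ fragments higher in every sEV group than in its cells.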

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

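The tests of Gm42047 and of ribosomal protein transcripts in this part were chosen after their values were seen; the test of secreted and membrane proteins and the splits of the samples were planned.

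The sEV-cell difference depended on the cell type in 324 genes by edgeR's interaction test. The 10 genes named for it were Stradb (adjusted p = 0.000106), AI506816 (adjusted p = 0.000108), Ftl1, Rpl9, Cdip1 and Rplp0 (adjusted p = 0.000112 each), Rps2 (adjusted p = 0.000125), Csnk1d (adjusted p = 0.000283), Rpl8 (adjusted p = 0.000317) and Gskip (adjusted p = 0.000331). Of 100 splits of the 18 libraries 4 gave as many genes, the real one included. The splits regrouped cell types separately among cells and among sEVs. Differences between cell types can thus become interaction calls in them, so they cannot decide on chance. The highest of the others gave 1110 genes, and a split that calls several times the real number points to a structure of the samples. Which libraries such splits grouped was not tested.

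Synaptic vesicle and postsynaptic genes differed between cultures with an estimated correlation in camera of limma. Their shift was higher by 2.57 log2 in astrocytes than in neurons (adjusted p = 0.027) and by 3.13 in microglia than in neurons (adjusted p = 0.0461). In neurons 11 of 18 genes fell, in astrocytes 2 and in microglia 0. Of the 18 genes 15 had 0 reads in microglia cells and 7 in astrocyte cells, where no fall can be seen, so this difference need not be one of packaging.

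Of 5 structural classes that no comparison used, 4 were more frequent in sEVs than in cells, and fusion isoforms were not (0.127 ± 0.0759% against 0.111 ± 0.0669%, n = 9; exact two-sided permutation p = 0.649). Antisense isoforms differed by 0.334 points (0.356 ± 0.682% against 0.0226 ± 0.00962%, n = 9; exact two-sided permutation p = 0.0005), although microglia sEV replicate 2 alone held 2.15%. Intergenic isoforms differed by 0.115 points (0.145 ± 0.176% against 0.0295 ± 0.00566%; exact two-sided permutation p = 0.00075) and genic isoforms by 0.185 points (exact two-sided permutation p = 0.001). Single libraries held much of both, with 0.563% intergenic in neuron sEV replicate 3, and genic isoforms at 0.421% in astrocyte sEV replicate 2, 0.532% and 0.709% in neuron sEV replicates 2 and 3 and under 0.003% in the 6 other sEV libraries. Isoforms with the IEJ mark, Gm42047 left out, differed by 0.0728 points (0.301 ± 0.0727% against 0.228 ± 0.0384%; exact two-sided permutation p = 0.015). Leaving Gm42047 out was chosen after its values were seen, and with it the difference was 1.15 points (exact two-sided permutation p = 0.00075). The smallest p possible is 0.00025. With groups of 3, no library was tested for lying far from the others of its group.

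Transcripts of secreted and membrane proteins were lower in sEVs. A score of 395 genes from gene families of secreted and membrane proteins minus 616 genes from families of cytosolic and nuclear proteins was lower in sEVs by -1.65 log2 (exact two-sided permutation p = 0.00025, the smallest possible), and by -1.74 in astrocytes, -1.18 in microglia and -2.01 in neurons. Low counts were excluded as the cause, since the difference was -1.85 among genes with a mean count of 20 or more. RNA quality was not excluded, since full-splice matches differed by -7.02 points, 3′ fragments by 4.55 points and genes at equal depth by -1067 over the same libraries. A candidate explanation is that mRNAs translated at the endoplasmic reticulum are kept out of sEVs. The sequencing pool stays open, because 0 pools hold both cells and sEVs and the pool cannot be told apart from the fraction.

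Gm42047, a predicted gene, took 6.76% of reads in astrocyte sEV replicate 1 (41564 reads; exact Clopper-Pearson 95% interval 6.69 to 6.82%) and 8.94% in neuron sEV replicate 1 (59712 reads; 8.87 to 9.01%), against 0.588 to 1.63% in the other astrocyte and neuron sEV libraries. In these 2 libraries 82.6% and 81.1% of the gene's reads fell on 1 isoform, which had 2 and 0 reads in the other replicates of its group and 173 and 0 in the 17 other libraries, so the first isoform was not confined to 1 library. A few molecules copied many times in library preparation are a candidate source. No biological explanation was tested.

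Ribosomal protein transcripts rose by 1.71 log2 more in neuron sEVs than in microglia sEVs. Camera called this difference with the preset correlation (adjusted p = 1.32e-18) but not with an estimated one (adjusted p = 0.157). Without Ftl1 and Gm42047 the difference was 1.75 ± 0.134 (SE over genes, which are not independent replicates). Both fits used TMM scaling, which already limits the weight of single genes. The result therefore cannot decide whether these 2 genes taking the counts was its cause. The difference between ribosomal protein and respiratory chain transcripts was 1.13 log2 larger in neurons (permutation p = 0.01, two-sided, with 0.005 the smallest possible). The permutation exchanged neuron and microglia labels separately within sEVs and within cells. Its p therefore also takes in differences between the 2 cell types themselves and cannot decide whether the rise was common to both groups. The ribosomal protein score alone did not pass (1.68 log2, p = 0.1 by the same permutation). RNA quality was not excluded, since full-splice matches differed by -8.39 points in neurons and -5.21 in microglia and 3′ fragments by 6.11 and 3.08 points. The cell type remains an open explanation that no test here addresses, and fraction and pool cannot be told apart within either culture.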

How the results depend on the processing

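Settings without Ftl1 and Gm42047, and without the 2 libraries rich in Gm42047, were chosen after the data were seen; the other settings were planned.

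No named gene or isoform, no called list shift and no share or correlation changed sign under any setting. For interaction and usage genes only adjusted p-values were compared between settings, so their signs were not followed. The balance of microglia gene calls turned from 221 higher and 751 lower to 666 and 519 without TMM. Counts of calls stayed within 1.5 times, shares within 1 SD and correlations within 0.05 in 134 of 160 settings other than leaving out single libraries, and in 469 of 540 of those. The cause was not tested for any of the changes below, except where fewer samples or genes explain it.

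DESeq2 called 1968 genes for astrocyte cells against other cells (1298 in the report) and 1001 for the interaction (324). The interaction also rose to 664 genes without TMM and 714 without the filter on low counts. Without that filter neuron isoforms numbered 1617 (2544), and usage fell to 9 genes in astrocytes and 16 in microglia, with more isoforms tested. Gene-level F tests called 142, 91 and 201 genes for usage in astrocytes, microglia and neurons. Without the 2 libraries rich in Gm42047 usage passed in 14 astrocyte genes, with fewer samples.

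The replicate block left 499 microglia isoforms and 18 and 14 usage genes in microglia and neurons. Correlations of same-numbered deviations between cells and sEVs lay between -0.0815 and 0.0795. All were under the minimum of 0.1 set for pairing, so the numbers were not taken as pairs. Yet 6 of 9 libraries correlated best with their own number, among them every neuron replicate, so a weak pairing was not excluded. The replicate block gave each number 1 effect over all groups, so it did not pair cells and sEVs within a culture. With an estimated correlation camera called 0 list shifts in place of 37, and the lowest adjusted p was 0.0947. Fry, which tests a list without the other genes, called 52 (10 higher, 42 lower), with 16 gained and 1 lost. Among those gained were EV biogenesis and surface proteins in astrocytes, microglia and neurons (adjusted p = 0.000158, 0.00298 and 2.52e-05 by fry). Fold change correlations among genes with a mean count of 20 or more were 0.442, 0.741 and 0.418.

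The full-splice-match difference was -1.84 points in astrocytes with each isoform counted once, and -13.05 in astrocytes and -13.6 in neurons without Ftl1. The 3′ fragment differences were 7.80, 7.13 and 12.3 points in astrocytes, microglia and neurons with each isoform counted once, and 6.71 and 8.47 points in astrocytes and neurons without Ftl1.

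Leaving out each library in turn gave 1100 to 1907 genes for astrocyte sEVs against cells, 583 to 1093 for microglia, 1872 to 2850 for neurons, 2495 to 2925 for the mean and 149 to 435 for the interaction. Among cells the ranges were 758 to 1481, 2701 to 3762 and 1714 to 2533 genes for astrocytes, microglia and neurons, and among sEVs 1307 to 1688, 3761 to 4253 and 2688 to 3274. Isoforms ranged from 715 to 1436, 318 to 863 and 1284 to 2532, usage from 6 to 37, 8 to 39 and 2 to 33 genes, and list shifts from 33 to 38. Full-splice-match differences ran from -7.55 to -6.40 points in the mean, -9.04 to -5.76 in astrocytes, -6.45 to -3.695 in microglia and -9.52 to -6.51 in neurons. Those of 3′ fragments ran from 4.31 to 4.77 in the mean, 4.03 to 5.04, 2.38 to 3.49 and 5.40 to 6.78. Genes at equal depth differed by -1202 to -912 in the mean, -1559 to -688 in astrocytes, -946 to -143 in microglia and -1638 to -1236 in neurons.

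The 100 named genes stayed past the threshold in 837 of 849 settings and in 1761 of 1800 that left out 1 library. The 12 exceptions were 9 genes by DESeq2, Acbd3 and Ythdc1 with the replicate block, and Ythdc1 without Ftl1 and Gm42047. The interaction genes and named isoforms passed in every setting that kept them, usage genes in 56 of 60 and 240 of 270, and lists kept their side in 338 of 405 and 1404 of 1458. Thinning every library to the smallest total gave 1754, 997 and 2574 genes for astrocytes, microglia and neurons (1660, 972 and 2570 in the report), so depth in this range did not lower them. In simulated counts few changes of 2-fold were recovered in any cell type alone, and the cause was not tested.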

Other observations

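The genes of the first paragraph were chosen after their values were seen; the splits of the samples were planned.

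Some labels had many reads in sEVs and few in cells, which need not mean that the transcripts were absent from cells. Whether fragments in sEVs account for the difference was not tested. With at least 50 reads in each sEV library of a cell type and at most 45 in the 9 cell libraries together, 23 labels met these limits in astrocytes, 3 in microglia and 52 in neurons, and 13 were shared by astrocytes and neurons. Gm20186 stood at 6590 ± 290 RPM in astrocyte sEVs and 7723 ± 579 RPM in neuron sEVs, with 22 reads in the 9 cell libraries. Rcc2 (3681 ± 824 RPM) and Unc119b (1196 ± 109 RPM), a lipid-binding trafficking gene, met them in astrocytes. So did Trak2 and Sall3, which with Rcc2 were named above among the largest gains in astrocyte sEVs. Mono-exonic isoforms held 47.7 ± 5.75% of the reads of these genes in astrocyte sEVs and 42.9 ± 9.60% in neuron sEVs, against 2.01% and 2.81% in the other genes, and 3′ fragments held 31.7% and 38.4% against 6.74% and 9.25%. In microglia sEVs mono-exonic isoforms held 47.9 ± 9.14% against 0.823%, but 3′ fragments only 4.22 ± 5.10% against 4.67%. These shares pool the reads of all labels, so they need not hold for single genes. Gm20186 had 11194 reads in astrocyte and 13930 in neuron sEVs, and Rcc2 had 6151 and 9661. The labels next in number of reads had 2022 and 2183. In microglia sEVs Gm43305 had 423 reads and the other labels 236 and 189.

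Other splits of the libraries were counted for each model. For sEVs against cells in 1 cell type there are only 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave as many calls. Genes numbered 1660 against 1 in the highest other split in astrocytes, 972 against 1 in microglia and 2570 against 0 in neurons. Isoforms numbered 1456 against 2, 877 against 2 and 2544 against 0, and usage genes 35 against 1, 42 against 2 and 35 against 0.

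For the other comparisons 100 splits were drawn. The mean of the 3 cell types gave 2778 genes against 202 in the highest other split, which argues against chance for that comparison. Among cells the numbers were 1298 against 782 for astrocytes, 3472 against 3045 for microglia and 2243 against 3059 for neurons, where 3 splits gave as many. Among sEVs they were 1636 against 2045 for astrocytes and 3176 against 3852 for neurons, with 3 splits each, and 4089 against 3858 for microglia. Splits that call as many genes as the real one point to a structure of the samples, and which libraries they grouped was not tested.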
